A study of Drosophila melanogaster with 2 samples.

How the data were processed

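Chromatin immunoprecipitation followed by sequencing was done on whole *Drosophila melanogaster* embryos collected from 0 to 24 hours, from a transgenic strain that makes a fusion of the zinc finger protein Ham (hamlet) with eGFP, and an antibody against GFP was used, per the labels. The chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The series held 2 biological replicates of a single group, so no treatment, genotype or stage was compared. The control libraries that the labels mention as possible controls were not analysed here. The aligner, the peak caller, its settings and the control used are not given in the sources used here.

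The files used were peak lists on genome build dm6, per the labels. Each replicate had a ranked list of candidate regions and a thresholded list taken from it, and the series had the same pair for both replicates pooled, plus a shorter thresholded list that the submitters called conservative, with its own ranked list. The ranking was by irreproducible discovery rate, per the deposited file descriptions. The signal value of a peak, used here as its height, is the authors' value as deposited, and nothing in the sources says that signal values of the 2 replicates share a scale. The score of a peak is the deposited value that rises with its reproducibility, up to 1000, and every thresholded peak had a score of at least 830. The −log10 of the irreproducible discovery rate was taken from the deposited ranked lists, where it reached at most 5.0, and was used only to check what the score minimum meant. The peaks of the sub-lists that the ranked lists also record were not used, because nothing names their sample. Every thresholded peak was a row of its ranked list with the same coordinates, and some rows that passed the score minimum were absent from the thresholded list; per the deposited file descriptions the thresholded lists had 1 more input than the ranked lists, whose nature is not stated. Read counts were not used here, so the depth of each library is unknown and no interval that needs it is given.

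The tests, the gene lists, the words and the rule for named genes were fixed before the data were examined. The named genes are ham, the genes nearest to the 20 pooled thresholded peaks of highest signal value that overlapped a thresholded peak of both replicates, the 3 members of each list with the highest peak, and the 3 genes with the most peaks. The 18 gene lists cover sensory organs, the Notch pathway, neuroblasts, neuronal function, glia, Hox genes, segmentation, mesoderm, trachea, gut, hemocytes and fat body, epidermis, germline, eye, EGFR, Wnt and Dpp signalling, Polycomb and corepressors, ribosomal proteins, and heat shock and histone genes. Older symbols (8) were replaced by those of the annotation. Genes came from Ensembl release 115 (BDGP6.54). No peak of any list ended beyond the RefSeq Release 6 length of its chromosome arm. Promoter, gene and word analyses used peaks on X, 2L, 2R, 3L, 3R, 4 and Y, a choice made after the data were seen, because the other scaffolds had no gene annotation in the table used.

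Overlaps of at least 1 bp were found with bedtools 2.31.1, and chance was set by 1000 random draws of as many peaks from the same replicate's ranked list (one-sided). A pooled thresholded peak was given the height of the ranked peak of each replicate that held its summit. These heights were compared between the replicates by Spearman's rank correlation, and by Pearson's r on the log2 scale. A promoter summit lay within 500 bp of an annotated start site, and thresholded summits were compared with the candidate regions that did not pass by Fisher's exact test (two-sided). In the promoter and arm comparisons, those regions are all candidate regions absent from the thresholded list, also the ones that passed the score minimum. Each summit was given to the protein-coding gene with the nearest start site. The number of genes of a list with a thresholded peak was compared with 10000 random lists matched on deciles of candidate regions per gene (two-sided permutation test, Benjamini-Hochberg adjustment over 18 lists). Words of 6 bases (2080 with reverse complements joined) and 10 fixed words were compared between windows of 50 bp on either side of the summit and windows centred 500 bp away on either side of the same summits (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over each family). Intervals on shares are 95% Wilson intervals and cover counting error only. The smallest p that the draws can give is 0.001 for overlaps and 0.0002 for lists before adjustment. Peaks, genes and windows are not independent replicates, so these tests describe the lists and not the spread between embryos.

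Alternatives to each choice were computed, including each replicate's own list (without the other replicate); several were added after the data were seen and are named as such in the closing part. While the data were explored, word scans of other peak subsets and word lengths were run, and they are not reported. A first version of the analysis departed from the fixed plan in several steps and was brought back to it after its output had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The statistics were tested on simulated data. Over 13000 simulated genes, a gene list with 4 times the hits was called in 85.0% of simulations. Unchanged lists were called in 0.0588%. The simulated lists were larger than all fixed lists but those of ribosomal proteins and of heat shock and histone genes. The share called therefore does not carry over to the smaller lists. For short words, over 2080 words, the planted word was called, 5 others besides it, and 0 when none was planted. Both sets of simulated windows had the same base composition, unlike the real ones. The simulation therefore cannot say how many words a shift in base composition alone would call.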

Results

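Peaks of the eGFP-tagged zinc finger protein Ham, a factor known for its part in sensory organ and neuron fates, were listed for whole embryos of 0 to 24 hours in 2 biological replicates. The pooled thresholded list held 1495 peaks, taken from 150585 candidate regions, and the shorter conservative list held 771, of which 747 were also in the pooled list. Replicate 1 had 516 thresholded peaks and replicate 2 had 1050. Of the pooled peaks, 1421 lay on the main chromosome arms and 74 on unplaced X scaffolds. The median pooled signal value was 91.7, the authors' own peak height, and the values ran from 2.04 to 1036. Peak widths had a median of 336 bp. Some pooled peaks overlapped each other, and merging these left 1420. The depth of the libraries is unknown, and the labels name the replicates as biological.

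The first comparison asked how far the 2 replicates found the same regions. Of the 516 peaks of replicate 1, 369 (71.5%) overlapped a peak of replicate 2, against a mean of 0.927% for random draws of candidate regions (one-sided permutation p = 0.001, the smallest the draws can give). Of the 1050 peaks of replicate 2, 376 (35.8%) overlapped a peak of replicate 1, against 0.387% by chance (permutation p = 0.001, again the smallest). With replicate 2's list shortened to its 516 highest peaks, as many as in replicate 1, the shares were 59.7% and 59.1%. Among the pooled peaks, 374 overlapped a thresholded peak of both replicates, 576 overlapped one of replicate 2 but none of replicate 1, 98 the reverse, and 447 overlapped none of either. Across the 1310 pooled peaks with a candidate region in each replicate, Spearman's rank correlation of the heights was 0.423 and Pearson's r on the log2 scale was 0.53. These are correlations across peaks, which are not independent replicates.

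**Figure D1:**
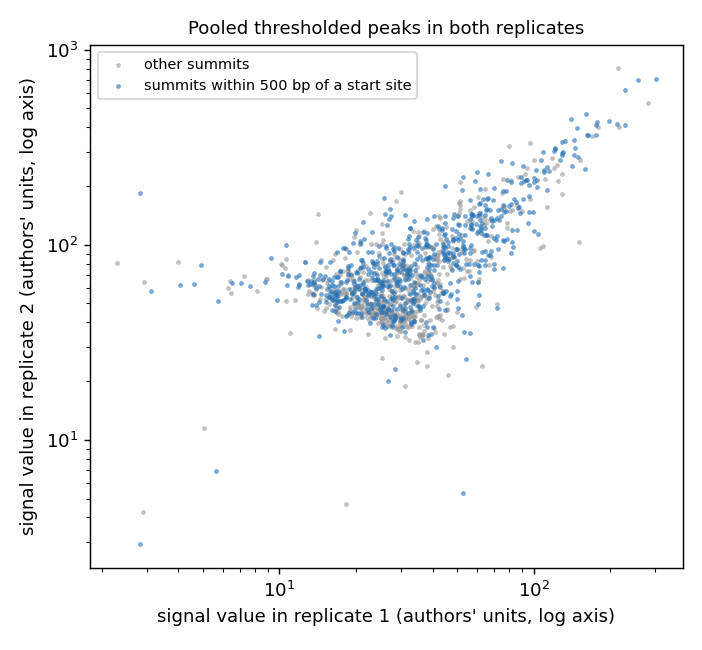
Signal value of each pooled thresholded peak on the main arms in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, with summits within 500 bp of a start site in blue and other summits in grey. The points are the 1250 main-arm peaks with a candidate region in each replicate.

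The 20 highest peaks shared by both replicates had signal values from 1036 to 493. The first was in an intron near CG11050 (FBgn0031836), on 2L from 6612557 to 6612879, with a pooled signal value of 1036 and values of 214 and 802 in replicates 1 and 2. The second had its summit at -92 bp from the start site of CG14100 (FBgn0036889), on 3L from 19590487 to 19590745, with a value of 1000.5. The third, of 954, lay at -134 bp from that of mRpL41 (FBgn0034001), which encodes a protein of the mitochondrial ribosome, on 2R from 15217623 to 15217882. Ugalt, a nucleotide sugar transporter gene, had a peak of 855 on X, at -39 bp from its start site, and HmgZ, which encodes an HMG-box chromatin protein, had one of 821. The next were ph-p (630), a Polycomb group gene, CG4004 (629), mRpS10 (626), another gene of the mitochondrial ribosome, eIF6 (615), a ribosome biogenesis factor, and Adf1 (604), a transcription factor gene. Peaks of 601 to 493 followed near CenG1A, CG32772, CG5611, Tcs5, Trl, Chro, CG7601, PNPase, CG8320 and Fkbp14. Trl encodes the GAGA factor and Chro a chromatin protein. Of these 20 peaks, 15 had their summit in a promoter. The peak nearest to CG4004 lay 5092 bp from its start site and within 500 bp of the start site of another annotated gene.

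Thresholded summits lay in promoters more often than other candidate regions. On the main arms 735 of 1421 summits (51.7%, 95% Wilson interval 49.1% to 54.3%) were within 500 bp of a start site, against 14.1% of the 145933 candidate regions that did not pass (Fisher's exact test, p = 1.06e-242). Introns held 408 summits (28.7%, against 37.2%), stretches between genes 176 (12.4%, against 24.3%), exons outside promoters and untranslated regions 85 (5.98%, against 20.3%), and untranslated regions 17 (1.20%, against 4.13%). The comparisons by height were added after the data were seen. The share was 69.6% among the 355 highest peaks and 36.8% among the 356 lowest. It was 62.3% among the 708 main-arm peaks of the higher-signal part of the list and 41.2% among the 713 of the lower-signal part (Fisher's exact test, p = 2.07e-15, adjusted p = 3.93e-14 over 19 tests).

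**Figure D2:**
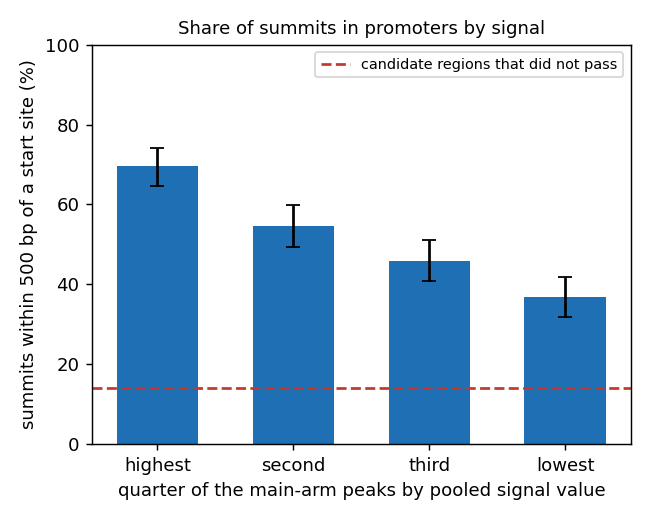
Share of summits within 500 bp of a start site (y axis, %) for the main-arm peaks divided into equal groups by pooled signal value (x axis), with 95% Wilson intervals as error bars. The share falls from 69.6% in the highest group to 36.8% in the lowest, and the dashed line marks the 14.1% of candidate regions that did not pass.

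Among the gene lists fixed in advance, ribosomal protein genes and Polycomb and corepressor genes held more thresholded peaks than random matched lists. Of 13968 protein-coding genes, 1165 (8.34%) were the nearest gene to at least 1 thresholded peak. Of 92 ribosomal protein genes, 30 had a peak, 4.85 times the random mean of 6.19 (permutation p = 0.0002, the smallest the draws can give; adjusted p = 0.0036). The highest were RpL7 (322), RpL34b (254) and RpS27 (248), and their summits lay at 31, -95 and -12 bp from the start sites. The list did not pass in lower-signal peaks (ratio 2.71, permutation test, adjusted p = 0.169), but the difference between higher-signal and lower-signal peaks did not pass either (23 and 9 peaks, Fisher's exact test, adjusted p = 0.116). It had 0 genes with a distal summit, farther than 500 bp from every start site. The random mean was only 1.97, with a central 95% of 0 to 5, so this did not pass (permutation p = 0.256). Of 24 Polycomb and corepressor genes, 8 had a peak, 4.09 times the random mean of 1.95 (permutation test, adjusted p = 0.0072). Among them were ph-p (630), Trl (545) and brm (390), and also gro. The fixed list also held trithorax group genes, among them Trl and brm, which encodes the ATPase of the Brahma remodelling complex. By the same permutation test this list did not pass in replicate 1's own peaks (ratio 5.80, adjusted p = 0.081), with random lists matched on gene length (ratio 2.72, adjusted p = 0.0708), in lower-signal peaks (ratio 4.08, adjusted p = 0.169) or in distal summits (ratio 4.69, adjusted p = 0.14). The difference between higher-signal and lower-signal peaks did not pass for it (9 and 4 peaks, Fisher's exact test, adjusted p = 0.478).

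Genes of EGFR, Wnt and Dpp signalling had 13 of 39 members with a peak, 2.07 times the random mean of 6.29, and the list did not pass the adjustment (permutation p = 0.0108, adjusted p = 0.0648). Its highest members were edl (157), spi (139), which encodes the EGFR ligand Spitz, and aos (127), which encodes the EGFR antagonist Argos. Of 11 alternatives it passed in 3. These were any gene body within 1 kb (ratio 2.63, permutation test, adjusted p = 0.0048), distal summits (ratio 2.77, adjusted p = 0.018) and Fisher's exact test on peaks (ratio 1.85, adjusted p = 0.0367). By the permutation test it did not pass in the conservative list (adjusted p = 0.317), higher-signal peaks (0.336) or lower-signal peaks (0.169). Nor did it pass in either replicate's own peaks, with the 5 kb limit (0.3) or with gene-length matching (0.0708).

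None of the other 15 lists passed, with adjusted p from 0.823 to 1. Sensory organ development, the process in which ham acts, had 4 of 36 genes with a peak (ratio 0.794), led by numb (157), ham (87.8) and ct (82.9). The Notch pathway had 5 of 35 (ratio 1.65), with gro (196), numb (157) and E(spl)m3-HLH (85.3). Neuroblast and temporal factors had 5 of 37 (ratio 0.828), with chinmo (316), brat (164) and hth (99.96). Neuronal function and axon guidance had 6 of 35 (ratio 1.07), with elav (274), side (102) and trio (74.3). Glia had 3 of 14 (ratio 2.05), namely moody (228), pnt (89.0) and drl (71.6). The Hox and homeobox list had 1 of 16 (ratio 0.418), hth. Segmentation had 4 of 30 (ratio 0.797), with ems (83.5), hry (80.4) and sob (74.5). Mesoderm and muscle had 6 of 35 (ratio 1.36), with sls (154), zfh1 (146) and tin (102). Trachea had 4 of 17 (ratio 1.40), with pyd (83.6), vvl (81.6) and Gasp (80.8). Gut and endoderm had 3 of 14 (ratio 1.76), namely bowl (154), fkh (104) and GATAe (93.1). Germline had 3 of 16 (ratio 1.86), namely bgcn (103), ovo (71.3) and bru1 (70.6). Hemocyte and fat body had 1 of 21 (ratio 0.445), ush (86.0), and epidermis and cuticle 1 of 18 (ratio 0.442), ovo. Heat shock and histone genes had 2 of 125 (ratio 1.65), Hsp27 (179) and Hsp83 (87.0), and eye and retinal determination had 0 of 15. The peaks given here for E(spl)m3-HLH, drl, hry, sob, vvl, bru1 and ush overlapped a thresholded peak of neither replicate. Those of ham, ct, brat, hth, side, pnt, ems, zfh1 and tin overlapped a thresholded peak of replicate 2 only. The same held for pyd, Gasp, bowl, fkh, GATAe, bgcn, ovo and Hsp83. That of trio overlapped a thresholded peak of replicate 1 only. The brat summit lay in no candidate region of replicate 1. Some peaks lay far from the start site of the gene, the farthest being those of hth (49822 bp), vvl (33865 bp) and side (30242 bp).

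**Figure D3:**
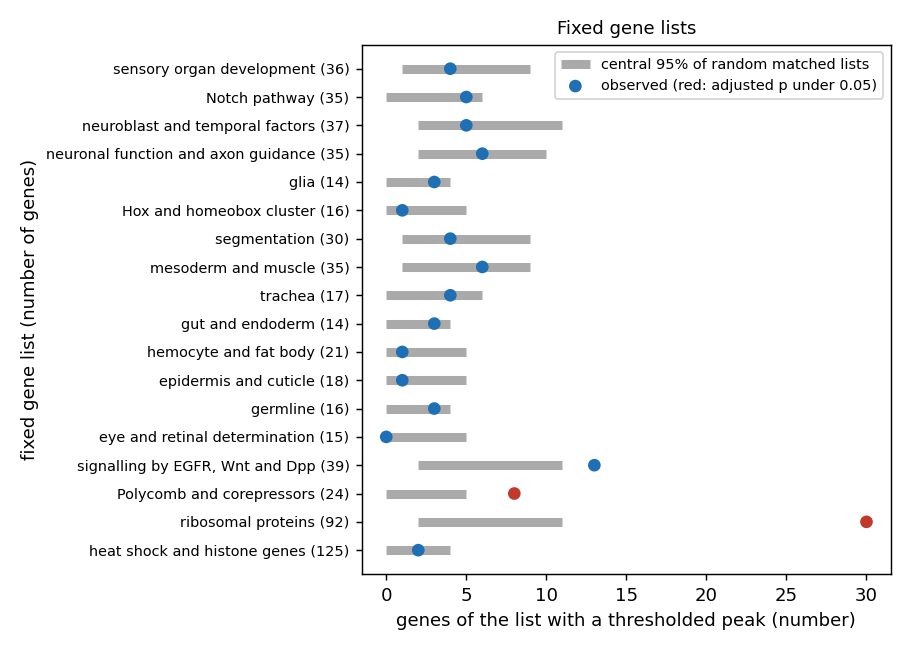
Number of genes with a thresholded peak in each fixed list (points, x axis) beside the central 95% of random lists matched on candidate regions per gene (grey bars), with the size of each list in brackets. Ribosomal proteins (30 genes) and Polycomb and corepressors (8 genes) are the points in red, with adjusted p under 0.05.

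The genes with the most thresholded peaks were Raf with 7, a kinase gene of the receptor tyrosine kinase pathway, CG6163 with 7, and CHES-1-like with 6, a forkhead gene. The summits of Raf lay between 2296355 and 2304111 on X, those of CG6163 between 11349447 and 11366604 on 3L, and those of CHES-1-like between 7697082 and 7707027 on X. Candidate regions nearest to these genes numbered 28, 52 and 40.

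Words made only of A and T were more frequent at summits than in the flanks of the same loci. Of 2080 words of 6 bases, 161 were higher at summits and 139 lower (adjusted p under 0.05). More words were lower than higher in the conservative list (336 and 223), in higher-signal peaks (408 and 243) and in replicate 2's own peaks (313 and 220). The same held with windows of 100 bp on either side (229 and 215) and against candidate regions (726 and 396). The 161 included 35 of the 36 words that hold only A and T. TTAAAA was in 27.9% of 1421 summit windows and in 15.2% of 2842 flank windows (Fisher's exact test, adjusted p = 7.38e-19), and ATTTTA in 25.3% and 13.5% (adjusted p = 1.18e-17). A and T made up 61.6% of the bases in summit windows and 56.8% in flanks. The shares were 66.6% and 56.3% in higher-signal peaks, but 56.7% and 57.4% in lower-signal peaks. In distal summits they were 58.9% and 58.5%. Among the 686 summits farther than 500 bp from every start site, 0 words passed by the same Fisher's exact test, and 0 passed among lower-signal peaks. The difference between these and promoter summits was not tested.

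Of the 10 words fixed in advance, 2 differed between summits and flanks. TATCGATA, the DNA replication-related element, was in 1.20% of summit windows and 0.422% of flanks (17 and 12 windows, Fisher's exact test, adjusted p = 0.0274), and GGTCACACT, the core of the M1BP motif, in 0.774% and 0.176% (11 and 5 windows, adjusted p = 0.0274). GATAA was in 20.3% and 17.9% (Fisher's exact test, adjusted p = 0.204), AGATAA in 6.62% and 6.05% (adjusted p = 0.627), and the longer GACAAGATA in 1 summit window and 0 flank windows. GAGAG, CAGGTA, CAGCTG, GAAGATGAG and TGACTCA did not pass (adjusted p from 0.307 to 1 by the exact test). By the same exact test GATAA passed in higher-signal peaks (22.3%, adjusted p = 0.0476), in replicate 2's own peaks (adjusted p = 0.0133) and against candidate regions (adjusted p = 8.24e-08), as did AGATAA, CAGGTA and CAGCTG against candidate regions, the last 2 as lower. GAGAG passed as lower at summits in the conservative list (9.25%, exact test, adjusted p = 0.00873), in higher-signal peaks (adjusted p = 0.00379) and in each replicate's own peaks (adjusted p = 0.0238 and 0.000979). In all these settings A and T bases were more frequent at summits than in the control. Their shares were 66.6% and 56.3% in higher-signal peaks, and 63.9% and 56.7% in replicate 2's own peaks. Against candidate regions they were 61.6% and 52.6%. The test does not correct for base composition, so such a shift cannot be told apart from a change in these words. In distal summits, where A and T made up 58.9% and 58.5%, GATAA was in 18.7% of windows in each. The counts of TATCGATA and GGTCACACT are small, and their test also did not correct for base composition. Of 1421 summits, 735 lay within 500 bp of a start site, and flanks were centred 500 bp away. Position near a start site therefore cannot be told apart from a gain of these 2 words at peaks. By the exact test neither passed with 25 bp (adjusted p = 0.162 and 0.679, with TATCGATA in 0.774% against 0.281%), in lower-signal peaks (0.905 and 0.497, with GGTCACACT in 0.982% against 0.281%) or in distal summits (0.936 and 1), where TATCGATA had 0 windows. In replicate 1's own peaks TATCGATA did not pass (0.706% against 0.118%, 3 windows and 1, exact test, adjusted p = 0.277) and GGTCACACT was lower at summits than in flanks (adjusted p = 1); GGTCACACT did not pass in the conservative list (0.408% against 0.068%, adjusted p = 0.249) or in higher-signal peaks (0.565% against 0.0706%, adjusted p = 0.113).

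**Figure D4:**
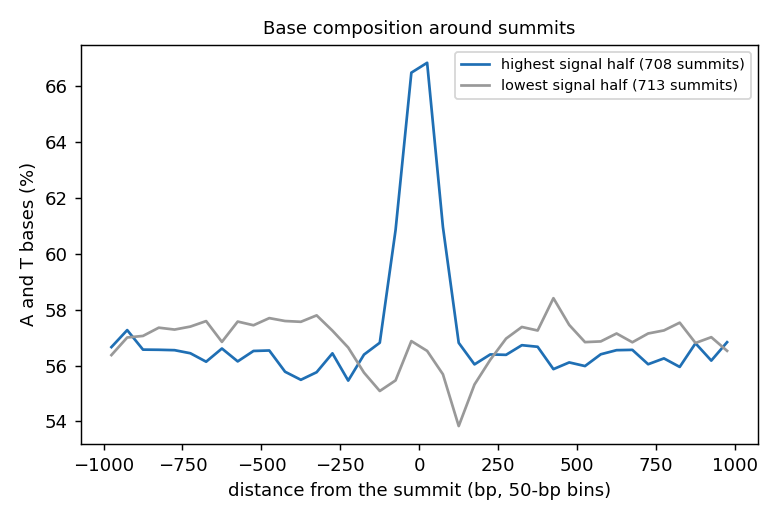
Share of A and T bases (y axis, %) in 50-bp bins around summits (x axis, distance in bp) for the 708 main-arm peaks of the higher-signal part of the list (blue) and the 713 of the lower-signal part (grey). The bins beside the summit reach 66.8% in the first and 56.9% in the second.

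The tagged gene was looked at as a check of the labels. ham (FBgn0045852), on the minus strand of 2L from 18762874 to 18792906, had 5 pooled thresholded peaks within 20 kb on either side, 3 of them in the gene body. The highest, from 18770484 to 18770819, lay in an intron 1106 bp downstream of a ham start site, with a signal value of 87.8 and rank 807. One from 18771763 to 18772098 had its summit at -173 bp from a ham start site (69.3), and one from 18781383 to 18781718 lay in an intron (62.8). Upstream of the gene lay the peaks from 18795944 to 18796279 (87.1), in the promoter of lncRNA:CR44904, and from 18806207 to 18806542 (53.8), in that of lncRNA:CR43817. Replicate 2's list held 3 peaks in the region and replicate 1's list 0, and none was in the conservative list.

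**Figure D5:**
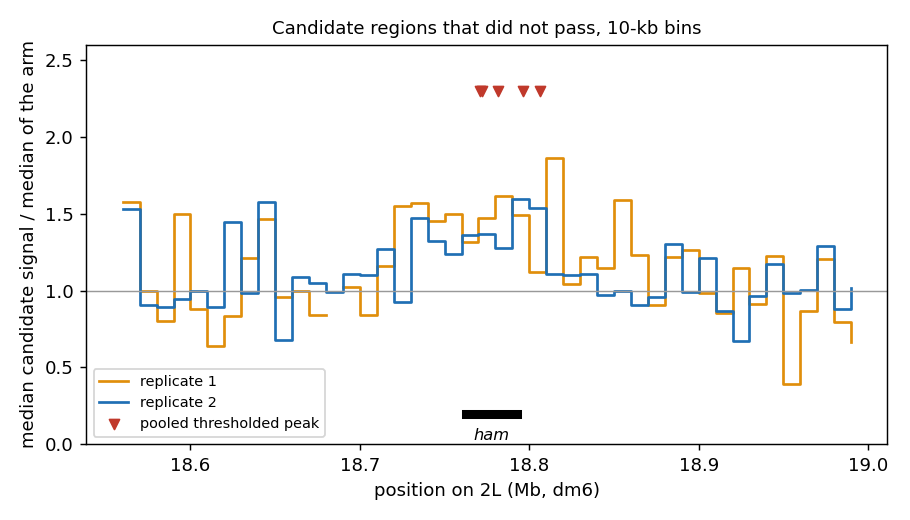
Median signal value of candidate regions that did not pass in 10-kb bins of 2L (x axis, Mb), divided by the median of the arm (y axis), for replicate 1 (orange) and replicate 2 (blue), with the 5 pooled thresholded peaks as triangles and the ham gene as a black bar. A gap is a bin with 0 candidate regions. The bins over ham lie above 1 in both replicates, from 1.32 to 1.61 in replicate 1 and from 1.28 to 1.60 in replicate 2. Bins away from the gene reach 1.86 in replicate 1 and 1.58 in replicate 2.

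The arm 3R held a smaller share of thresholded peaks than of other candidate regions, 21.96% against 25.8% (312 peaks, Fisher's exact test, adjusted p = 0.00621). The shares on X (17.9% against 17.6%), 2L (19.8% against 17.7%), 2R (18.0% against 18.6%) and 3L (22.1% against 19.8%) did not pass, with adjusted p from 0.0996 to 0.817. The other candidate regions include 112 that passed the score minimum but were absent from the thresholded list, 46 of them on X. The share on X therefore depends on that unexplained omission. Chromosome 4 had 0 peaks and Y had 3. By the exact test 3R did not pass in replicate 2's own peaks (22.05% against 25.5%, adjusted p = 0.0695) or in lower-signal peaks (22.6% against 25.8%, adjusted p = 0.142), where 3L passed instead (24.3%, adjusted p = 0.0244). Against arm length 3R did not pass (exact test, adjusted p = 0.323) while 2L, 4 and Y did. Lengths entered that test in kilobases as if they were counts, so its p depends on the unit. Chromosome 4 held 0.98% of the length but 0.0404% of the other candidate regions, and Y 2.67% but 0.499%. Against those candidate regions neither 4 nor Y passed.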

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

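On unplaced X scaffolds, which carried no genes in the annotation used, lay 74 pooled thresholded peaks, which the promoter, gene, word and arm comparisons left out and the replicate overlap kept. Replicate 1's list had 91 such peaks and replicate 2's list 16, and on the main arms alone 83.3% of replicate 1's peaks overlapped one of replicate 2. Among pooled candidate regions, 169 passed the score minimum but were not in the thresholded list. Their median signal value was 92.9, against 91.7 for those kept. Of them, 112 were on the main arms, 46 of these on X. Another 57 were on scaffolds assigned to Y or to no chromosome, where 0 thresholded peaks lay. The highest of all 169 had a value of 838. In replicate 1, 172 of 688 passing regions were left out (25%), 81 of them on X, and in replicate 2, 69 of 1119 (6.17%), 3 of them on X. No explanation was tested for either.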

How the results depend on the processing

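Added after the data were seen: the lower-signal peaks, distal summits (farther than 500 bp from every start site) for the gene lists but not for the words, low-signal peaks left out, main arms only, and single replicates at ham. The promoter share kept direction and threshold under every alternative run. The overlap p stayed at the smallest value the draws allow, so it could not show a change; the shares ran from 59.7% to 83.3% for replicate 1 in replicate 2 and from 31.0% to 59.1% for the reverse, with 59.7% and 59.1% at equal list lengths. The cause of the changes below was not tested. The peak count was 1420 with overlapping peaks merged, 771 in the conservative list, 747 by signal, and 516 to 1050 without a replicate. Spearman's rank correlation of the replicates' heights was 0.569 for the conservative list and 0.506 on the main arms. Lists past the threshold numbered 0 for lower-signal peaks, 1 with gene-length matching, 1 for distal summits, and 1 to 2 without a replicate. Words higher at summits numbered 243 for higher-signal peaks, 0 for lower-signal peaks, 77 with 25 bp, 396 against candidate regions, 0 for distal summits, and 146 to 220 without a replicate. Words lower at summits numbered 336 in the conservative list, 408 for higher-signal peaks, 0 for lower-signal peaks, 23 with 25 bp, 229 with 100 bp, 726 against candidate regions, 0 for distal summits, and 142 to 313 without a replicate. At ham there were 3 peaks in the gene body and 0 to 3 without a replicate. Arms past the threshold numbered 3 against arm length, a number that depends on the unit of length, and 0 to 1 without a replicate.

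For single lists (18 lists, 198 values), 161 kept direction and threshold, 5 lost and 3 gained a call, and 29 changed direction, each from or to a ratio that did not pass. Distal summits gave ratios of 0.664 for Notch, 1.19 for neuroblasts, 1.14 for segmentation, 0.908 for gut, and 0 for ribosomal proteins and for heat shock genes. Lower-signal peaks gave 1.24 for segmentation and 0 for gut. Higher-signal peaks gave 1.01 for neuroblasts, 0.727 for neuronal function and 0 for trachea. The conservative list gave 0.766 for neuronal function. Gene bodies gave 1.27 for Hox and 0.241 for heat shock genes. The 5 kb limit gave 0.779 for neuronal function and 0.821 for germline. Gene-length matching gave 0.869 for neuronal function, 1.19 for segmentation and 0.422 for heat shock genes. Fisher's test on peaks gave 0.526 for neuronal function, 0.797 for mesoderm, 0.657 for trachea and 0.699 for germline. Without a replicate, sensory organs had 1.06 to 1.31, neuronal function 0.954 to 1.30, trachea 0 to 1.01, gut 0 to 2.38 and germline 0 to 1.73.

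For the 10 fixed words (90 values), the share at summits moved below or above that of the control for AGATAA (5.19%), GAGAG (14.9%) and CAGCTG (5.19%) in lower-signal peaks, for CAGCTG with 100 bp (9.85%), for TGACTCA against candidate regions (0.774%), and for GATAA (18.7%), CAGGTA (2.04%), CAGCTG (5.25%) and TATCGATA (0%) in distal summits. Without a replicate, shares were 1.16% to 1.18% for TGACTCA and 0.235% to 0.677% for GGTCACACT. Depth is unknown, so it cannot be said what it limits. No paired analysis was possible because the series has a single group.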

Other observations

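Of the tests in this part, those of the ham locus and of the peaks of very low signal were chosen only after the result was seen; both tests of promoter peaks were written before, but the set of start sites of the head-to-head test was widened from coding to all genes after a first run. No biological explanation was tested, since the design has a single group.

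Strong peaks lay mostly at promoters. If active promoters were recovered without regard to Ham, ribosomal protein genes, active in every cell, would hold promoter peaks more often than other genes, and they did: 31 of 92 (33.7%) against 6.59% of all coding genes, 5.11 times as many (Fisher's exact test against the other coding genes, p = 9.29e-15). The genes and thresholded peaks are largely those of the ribosomal protein list result above, so this test adds no separate support. Unspecific recovery of active promoters stays open as a candidate explanation, and no immunoprecipitation from untagged embryos was analysed here that could separate it from binding by Ham. Head-to-head gene pairs, with opposite start sites within 1 kb, lay beside 44.2% of thresholded and 22.8% of other candidate promoter summits (ratio 1.94, Fisher's exact test, p = 5.01e-36). The ratio was 2.01 with coding genes alone. Only promoter summits, of all heights, entered this test, so it cannot say why strong peaks lay at promoters. The nearest gene is uncertain at head-to-head pairs.

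Around ham, candidate regions that did not pass had a higher median signal value than in any of the windows of the same length (70033 bp, every 10 kb, at least 20 candidate regions) on 2L away from the gene, in both replicates (percentile 100 in each). The median was 15.6 in replicate 1, where the highest other window had 15.3, and 22.2 in replicate 2, where it had 21.9. The ratios to the typical window were 1.44 and 1.35. Extra copies of the tagged locus in the transgenic strain may raise the local signal in this way, which would also lift the 5 thresholded peaks there. The labels do not say how many copies the strain carries, and open chromatin across the locus was not tested.

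The pooled list held 66 thresholded peaks with a signal value below 21.4, the median of all candidate regions, down to 2.04. All of them (100%) lay within 500 bp of a candidate region of at least double their height, against 0.56% of the other 1429 thresholded peaks (Fisher's exact test, p = 1.05e-106). The rule is easier to meet for low peaks, so candidate regions of like signal that did not pass were also taken: 49.9% of 1272 met it (Fisher's exact test, p = 7.09e-20), a comparison added once the first result was seen. A pooled peak called on the shoulder of a stronger summit is a candidate explanation.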
